A study of Homo sapiens with 7 samples.

How the data were processed

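The data are 7 libraries of single cells from cultures of the CCD18co fibroblast line, 1 per condition, made from cells released by trypsin with a 3' single-cell kit of 10x Genomics, per the labels' protocols. Conditions were taken from the labels alone: DMSO, used as the control, and IL36, TNFa, IL1b, TGFb, TL1a and OSM. Whether the stimulated cultures also received DMSO, and doses, times and isoforms, are not given in the sources used here.

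The deposited files hold raw UMI counts per gene and cell barcode that Cell Ranger made and filtered to cell barcodes, per the file headers and the submitters' processing notes. The notes list version 2.1.1 and the file headers software version 3.0.2, so the version that made the counts is unsure. The genome build, the annotation release and the use of strand are not given in the sources used here, so genes are given by symbol and Ensembl identifier without coordinates. Of 33538 identifiers 33456 occur in GENCODE release 29, and 24 symbols stood on more than 1 identifier.

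All steps were computed from these counts with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last only for TMM factors. Barcodes with fewer than 500 detected genes or more than 20% mitochondrial UMIs were removed. This kept 2483 of 2502 barcodes in the control, 2199 of 2208 (IL36), 2904 of 2924 (TNFa), 2240 of 2309 (IL1b), 2302 of 2316 (TGFb), 2387 of 2405 (TL1a) and 2817 of 2825 (OSM). Of the 69 barcodes removed from the library labelled IL1b 63 were under the gene minimum. Median genes per cell ran from 6821 to 7657, and no 2 libraries held identical counts. Doublets were not called.

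UMIs were summed over the kept cells of each library and scaled to the library total as CPM, and log2 folds were taken after adding 1 CPM to both sides. A gene was measured in a comparison if it had at least 10 CPM in 1 of the 2 libraries, and was counted as higher or lower from 2-fold, on the log2 fold with that addition. Folds without the addition carry exact Clopper-Pearson intervals on the split of the 2 counts. At this depth a gene at 15.1 CPM in the control, such as SST, has 1601 UMIs, so intervals are narrow. They treat each UMI as an independent draw and so leave out differences between cells, although 10 cells held 90.1% of these SST UMIs. They also leave out the differences between cultures, which 1 library per condition cannot show. A total of 129 sex-linked genes were left out of all gene comparisons. Libraries with known folds were also simulated by Poisson draws from the control profile, without variation between cells or cultures. In each of the 6 comparisons 100 of 100 genes set 4-fold higher or lower and 0 of 100 set 1.3-fold higher or lower were counted, over 9198 to 9232 genes. No unchanged gene was counted, and intervals covered the true fold in 94.5% to 95.3% of genes. The simulation checks the computation and not the error of the size rule or the intervals in the real libraries.

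The 26 gene lists with 499 entries were fixed before the files were opened. Each list gave the number of measured members higher and lower by 1.5-fold, the median log2 fold, and the place of that median among 10000 random lists matched on expression in 20 bins. Random lists do not carry the shared movement of list members, so a place beyond all of them is no measure of chance. Named genes were the 10 highest and 10 lowest log2 folds per comparison among the genes counted by the size rule, without mitochondrial, ribosomal protein, sex-linked and clone-named genes, besides up to 4 members with the largest folds of each list described and other list members whose value is given. Genes that set 1 library apart were at least 2-fold from each of the other 6, with the 5 furthest named on each side. Similarity of 2 libraries was the Pearson r of their log2 folds over genes with a mean of at least 10 CPM, set beside 100 Poisson simulations in which both were drawn without change from the control.

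For shares of cells, each cell was thinned at random to 13500 UMIs, and shallower cells were left out: 237 (control), 182 (IL36), 278 (TNFa), 224 (IL1b), 133 (TGFb), 126 (TL1a) and 77 (OSM). Shares have exact binomial intervals over cells of 1 library. A cell was put in the cycling class from 5 thinned UMIs over the G2M list. Markers of 7 cell types were summed as levels, and cells were not clustered.

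Alternatives were TMM factors, median-of-ratios size factors as in DESeq2 but computed in Python, totals without mitochondrial and ribosomal protein genes, minimum levels of 1 and 50 CPM, additions of 0.1 and 5 CPM, no cell filter, a filter at 2000 genes and 10% mitochondrial UMIs, leaving out the 5% of cells with the most UMIs, equal weight for each cell, cells outside the cycling class only, limits of 1.5-fold and 3-fold, and other depths and a limit of 10 UMIs for shares.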

Results

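Single-cell transcriptomes were collected from CCD18co cells, a fibroblast line derived from normal human colon, cultured with the solvent DMSO or with 1 of 6 cytokines, of which the labels call all but OSM recombinant. The cytokines named in the labels were interleukin-36 (IL36), tumour necrosis factor (TNFa), interleukin-1 beta (IL1b), transforming growth factor beta (TGFb), TNF-like ligand 1A (TL1a) and oncostatin M (OSM), and the stated purpose was to examine pro-fibrotic signatures. Each condition was 1 library (n = 1), and the labels give no dose and no time. The 7 libraries held 17332 kept cells of 17489 barcodes, between 2199 cells (IL36) and 2904 cells (TNFa), with 100405678 to 122973222 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule) per library. The median per cell ran from 38254 UMIs (OSM) to 50681 UMIs (IL1b).

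Levels are UMI counts summed over the kept cells of a library and scaled to the library total (CPM). Folds are ratios of CPM over the DMSO control, and the range in parentheses after a fold is its exact 95% interval, which covers counting error only. With 1 library per condition no difference has a replicate check, so no test between conditions was made, and each statement describes these libraries rather than the cytokines. Genes were counted as higher or lower by a fixed size rule of 2-fold with at least 10 CPM in 1 of the 2 libraries, and members of a gene list by 1.5-fold. The targets of TGFb signalling were not higher in the library labelled TGFb, and the targets of gp130, the signalling chain of the oncostatin M receptor, were not higher in the library labelled OSM. For this reason every condition is named throughout as its library is labelled.

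**Figure D1:**
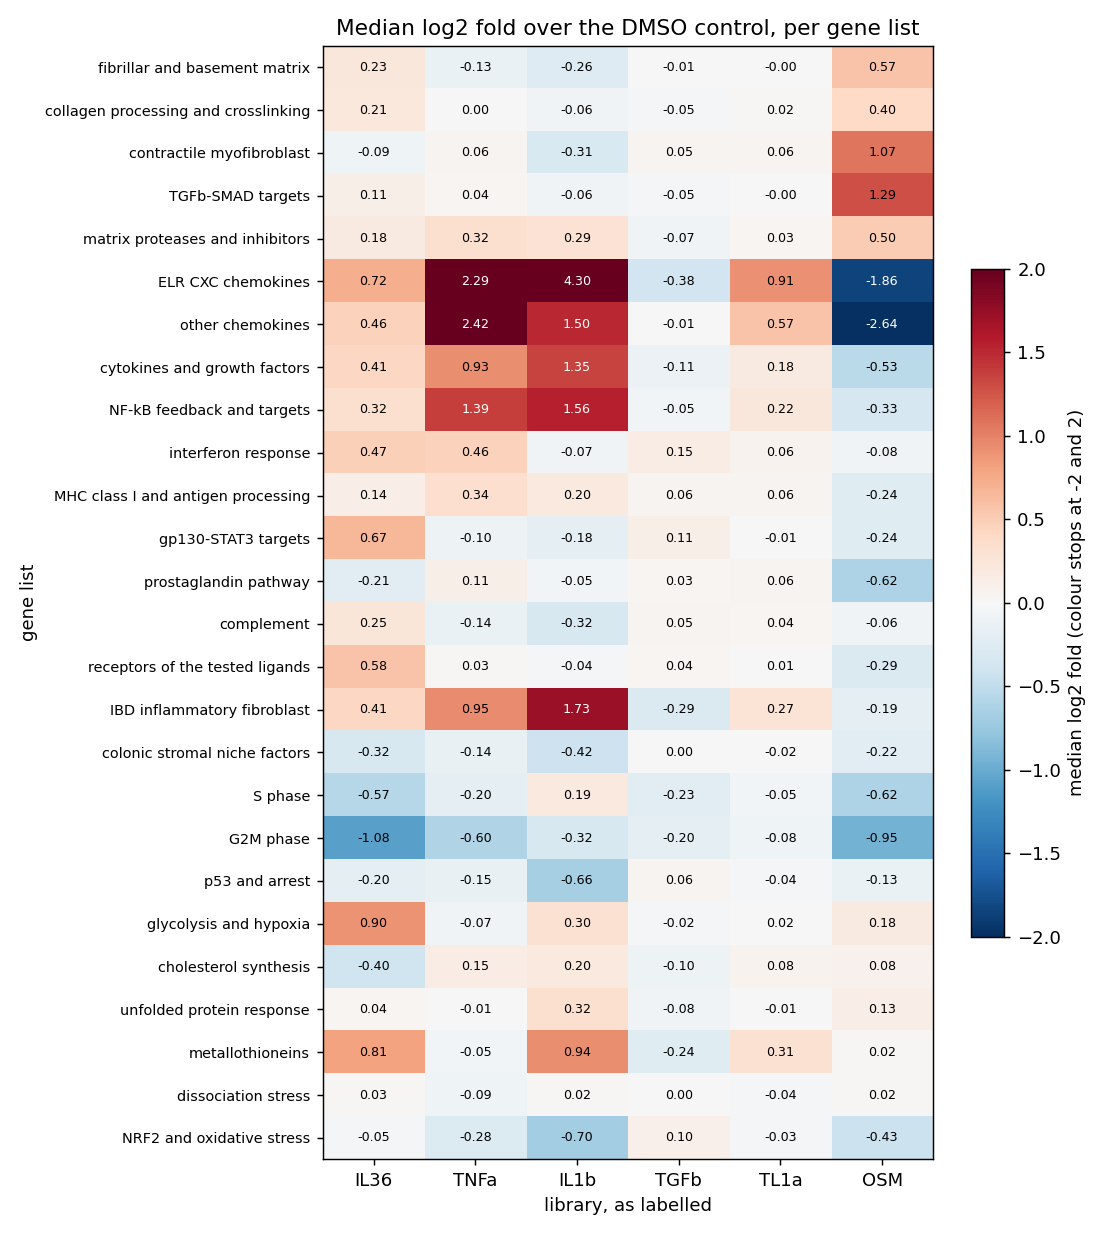
Median log2 fold over the DMSO control of the measured members of each of 26 gene lists (vertical axis) in each stimulated library (horizontal axis, as labelled), with the value printed in each cell and 1 library per condition. The chemokine lists reach 4.30 in the library labelled IL1b, the TGFb-SMAD list 1.29 in the library labelled OSM and the gp130-STAT3 list 0.67 in the library labelled IL36, while medians run from -0.38 to 0.15 in the library labelled TGFb and from -0.08 to 0.91 in that labelled TL1a.

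Genes of the inflammatory NF-kB pathway and chemokines stood far above control in the library labelled TNFa. CXCL8 (ENSG00000169429), the main neutrophil chemokine, was 12.7-fold (12.6 to 12.8) higher, from 695 to 8857 CPM. BIRC3 (ENSG00000023445), an inhibitor of apoptosis induced by NF-kB, was 35.8-fold (29.9 to 43.3) higher, the granulocyte and macrophage growth factor gene CSF2 (ENSG00000164400) 20.1-fold (18.7 to 21.7) and TNFAIP3, a feedback inhibitor of NF-kB, 9.19-fold (8.77 to 9.63). CXCL10 and CXCL11, chemokines for T cells, were 6.87-fold (6.64 to 7.11) and 14.1-fold (11.7 to 17.1) higher. Of 23 measured NF-kB targets 21 were higher and 0 lower, with a median log2 fold of 1.39, above all 10000 random lists matched on expression. The 6 measured ELR chemokines, which attract neutrophils, were all higher (median 2.29), as were 14 of 20 cytokines and growth factors, with 1 lower, among them IL6 (5.75-fold), IL32 (5.38-fold) and INHBA (4.65-fold). Class I antigen presentation genes had a median of 0.34 with 4 of 14 higher, led by the peptide transporter TAP1 (1.95-fold), and the interferon list one of 0.46 with 5 of 15 higher, but -0.06 over its members from 50 CPM. IFIT1, an interferon-induced gene, was 3.72-fold (3.40 to 4.08) lower.

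The other named genes higher in this library were C15orf48 (18.7-fold), the macrophage elastase gene MMP12 (11.3-fold), BCL2A1 (15.3-fold), CXCL6 (6.89-fold) and MRGPRX3 (14.6-fold), and 10 cells held 33.0% of its MMP12 UMIs. Those lower were the kinesin gene KIF26B (3.67-fold, 3.58 to 3.76), PKDCC, COLEC10, ADAMTS19, LNX1, the lysophosphatidic acid receptor gene LPAR3, GPRC5A, AKAP6 and PLAT, tissue plasminogen activator, which was 3.09-fold (3.05 to 3.13) lower from 791 CPM. Matrix genes went both ways, with COL8A1 (3.02-fold) and the matricellular gene TNC (2.89-fold) higher and COL1A1 at 0.791-fold and COL3A1 at 0.727-fold of control. The median of that list was -0.13 and its mean 0.12, which differ in sign. By the 2-fold rule 156 genes were higher and 81 lower. Scaling by TMM factors in place of library totals moved the median of all measured genes from -0.09 to 0.02 and the counts to 192 and 56, so that the share of higher genes was 77.4% in place of 65.8%.

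The ELR chemokines and the list of cytokines and growth factors stood further above control in the library labelled IL1b than in that labelled TNFa, while 5 of 7 other chemokines were higher against 6 of 7 there, with 1 lower in each. CSF2 was 181-fold (168 to 194) higher and CSF3 (ENSG00000108342), the granulocyte growth factor, 89.5-fold (83.2 to 96.4). CXCL2 (ENSG00000081041) was 51.0-fold (48.9 to 53.1) higher, CXCL3 32.6-fold (31.8 to 33.4), CCL20 59.3-fold (54.0 to 65.3) and the inflammatory cytokine IL6 (ENSG00000136244) 26.4-fold (25.8 to 27.0). CXCL8 reached 16625 CPM, 23.9-fold (23.7 to 24.1) its control level, and the collagenase-activating protease MMP3 30002 CPM against 5294. All 6 measured ELR chemokines were higher, with a median log2 fold of 4.30, and so were 19 of 23 NF-kB targets (1.56), 13 of 20 cytokines and growth factors, with 1 lower (1.35, against 0.93 in the library labelled TNFa) and 10 of 13 genes linked to inflammatory fibroblasts of bowel disease (1.73), including IL11 (7.93-fold), IL24 (10.4-fold) and MMP1 (3.38-fold). PTGS2, the inducible enzyme of prostaglandin synthesis, was 10.7-fold (10.48 to 10.9) higher, while the constitutive PTGS1 was at 0.437-fold of control.

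Further named genes higher here were C15orf48 (72.2-fold), SERPINB7 (63.0-fold) and MMP12 (38.9-fold). Lower were LNX1 (8.93-fold, 8.21 to 9.74), the protease gene ADAMTS19 (7.27-fold, 6.89 to 7.67), KIF26B (6.67-fold, 6.46 to 6.89), INSC, FRY, IFIT1, ADAMTS9, PKDCC, PDK4, a kinase that restrains pyruvate oxidation, and the hormone gene SST. The contractile list had a median of -0.31, or -0.10 with TMM factors, with 3 of 17 members lower, among them smooth muscle actin ACTA2 at 0.579-fold and TAGLN at 0.591-fold of control. COL3A1 was at 0.468-fold and the proteoglycan gene VCAN at 0.376-fold, whereas elastin (ELN, 20.2-fold), the hyaluronan synthase HAS2 (6.998-fold) and TNC (3.81-fold) were higher, so the matrix list took no single direction: its median was -0.26, its mean -0.01 and its median with TMM factors 0.02.

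By the 2-fold rule 228 genes were higher and 351 lower in the library labelled IL1b, but these counts depended on the scaling. The genes counted as higher took 12.2% of its UMIs against 2.24% in the control, which lowers every other gene's share. With TMM factors 318 genes were higher and 202 lower, and the share of higher genes was 61.2% in place of 39.4%. The median of all measured genes moved from -0.14 to 0.07.

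Log2 folds of the libraries labelled TNFa and IL1b had a Pearson r of 0.85 across 9037 genes, which are not independent replicates. Libraries simulated as unchanged against the same control gave 0.52, and the covariance was 0.152 against a simulated 0.000576. Of the 146 and 197 higher genes measured in both libraries 125 were shared where independent lists would share 3.10, and 74 lower genes were shared against 3.07. The control is a single library and could not be split, so part of this excess may come from the shared control. Set directly against each other, the library labelled IL1b had more CSF3 (20.1-fold, 19.5 to 20.8), CSF2 (8.99-fold, 8.85 to 9.13), CXCL1 (5.66-fold, 5.64 to 5.69) and IL6 (4.59-fold, 4.55 to 4.63). It had less CXCL11 (4.71-fold lower, 4.21 to 5.28), CXCL10 (2.72-fold, 2.66 to 2.79) and VCAM1 (1.94-fold, 1.88 to 1.995), an adhesion molecule for leukocytes, and CCL2 differed by only 1.09-fold (1.08 to 1.09).

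**Figure D2:**
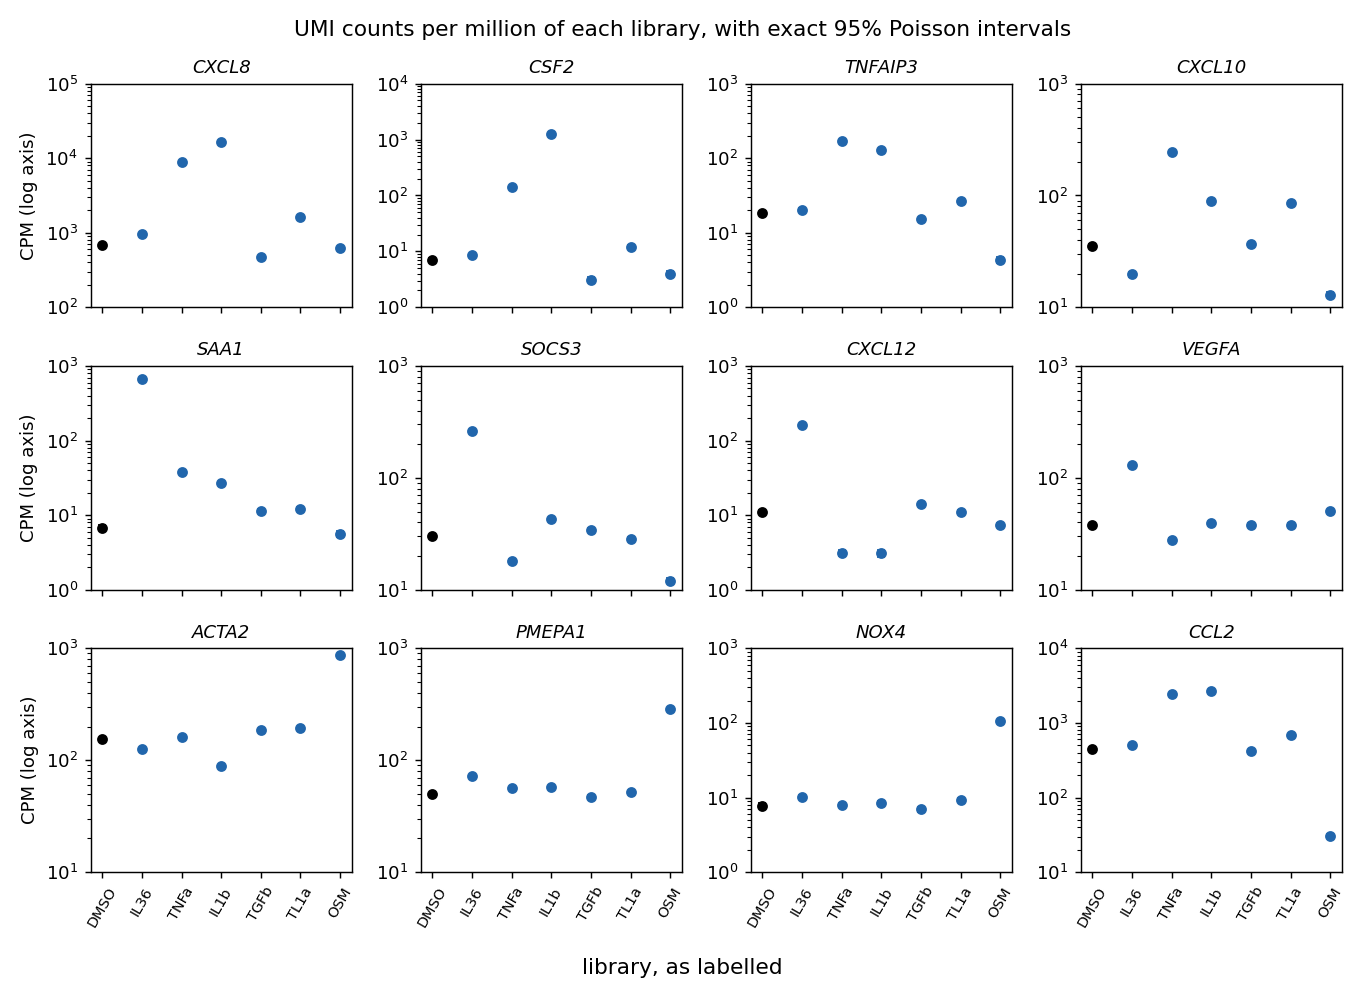
Summed UMI counts scaled to the library total in CPM (vertical axes, logarithmic) of 12 genes in the 7 libraries (horizontal axes, as labelled, the DMSO control in black), with exact 95% Poisson intervals that are mostly narrower than the points. CSF2 is highest in the library labelled IL1b at 1259.5 CPM, SOCS3 in the library labelled IL36 at 259.8 CPM and ACTA2 in the library labelled OSM at 866 CPM.

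Contractile, matrix and TGFb-SMAD target genes were higher in the library labelled OSM, and chemokine genes lower. ACTA2 (ENSG00000107796), the marker of myofibroblasts, was 5.59-fold (5.50 to 5.69) higher, the feedback inhibitor of TGFb signalling PMEPA1 (ENSG00000124225) 5.86-fold (5.69 to 6.03) and the oxidase NOX4 13.7-fold (12.7 to 14.7). Fibronectin (FN1) was 4.31-fold (4.27 to 4.34) higher and COL1A1 1.84-fold (1.83 to 1.85). The TGFb-SMAD list had 13 of 19 measured members higher and 1 lower, with a median log2 fold of 1.29. In the contractile list 13 of 19 were higher (median 1.07), in the matrix list 14 of 28 (0.57) and in the collagen processing list 4 of 15, with 1 lower (0.40). The first 3 of these lay above all 10000 matched random lists. Markers of smooth muscle cells or pericytes summed to 698 CPM there against 443 in the control, with MYH11 at 11.3 against 2.11 and ACTG2 at 486 against 200.3, both also in the contractile list, but RGS5 at 64.2 against 130.2.

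LDLRAD4, a further inhibitor of TGFb signalling, was 19.5-fold (17.8 to 21.4) higher in the library labelled OSM, and the muscle actin genes ACTC1 27.4-fold (24.4 to 30.9) and ACTA1 329-fold (128 to 1209.6). ACTA1 had 4 UMIs in the control, and 10 cells held 92.6% of its UMIs in the library labelled OSM. Other leading genes were MDFI (145-fold), KANK4 (188-fold), ODAPH (49.0-fold), ANOS1 (16.3-fold) and LMCD1 (14.3-fold), with 25.4% of the ODAPH UMIs in 10 cells. Lower were the monocyte chemokine CCL2 (14.6-fold, 14.1 to 15.2), the eotaxin gene CCL11 (11.1-fold, 10.1 to 12.2), CCL7 (7.41-fold, 6.74 to 8.17), IL1B (6.65-fold, 6.31 to 6.999), VCAM1 (7.06-fold, 6.49 to 7.70) and the fibroblast transcription factor TCF21 (6.90-fold, 6.69 to 7.11), besides IFIT1, ADAMTS9, CEMIP and ALDH1A2. In the control 10 cells held 27.4% of the CCL7 UMIs. ELR chemokines had a median of -1.86 with 4 of 6 lower, although CXCL8 was at 0.902-fold of control, and 7 of 18 NF-kB targets were lower and 1 higher. The gp130-STAT3 list had a median of -0.24 with 6 of 21 lower and 1 higher. SOCS3, the feedback inhibitor that gp130 signalling induces, was at 0.4004-fold (0.375 to 0.427) of control. In all, 313 genes were higher and 264 lower.

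Genes of the gp130-STAT3 list were higher in the library labelled IL36. The acute-phase protein gene SAA1 (ENSG00000173432) was 99.8-fold (92.7 to 108) higher, SOCS3 (ENSG00000184557) 8.63-fold (8.32 to 8.96), the stromal chemokine CXCL12 14.7-fold (13.9 to 15.6) and LBP, which binds bacterial lipopolysaccharide, 10.9-fold (10.0 to 11.8). Its co-receptor CD14 was 9.98-fold (9.46 to 10.55) higher and the complement factor CFB 16.0-fold (12.9 to 20.04). The gp130-STAT3 list had 11 of 21 measured members higher and 1 lower, with a median log2 fold of 0.67 above all 10000 matched random lists, including JUNB (3.08-fold), BCL3 (2.84-fold) and the oncostatin M receptor gene OSMR (2.25-fold), while the related receptor gene LIFR was at 0.454-fold of control. Genes of glycolysis and the hypoxia response were higher in 12 of 16 cases (median 0.90), led by VEGFA (3.46-fold), BNIP3 (2.93-fold), ENO2 (2.53-fold) and PGK1 (2.40-fold), and AK4, a mitochondrial adenylate kinase, was 12.7-fold (10.98 to 14.7) higher. Cholesterol synthesis genes had a median of -0.40, below all matched random lists, with 3 of 18 lower by 1.5-fold.

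CHI3L2 (40.6-fold), CCL20 (12.1-fold) and C2orf83, with 1458 UMIs against 2 in the control (739-fold, 204 to 6107), completed the leading genes of this library, and 10 cells held 48.1% of its CCL20 and 30.6% of its CHI3L2 UMIs. Lower were the transporter gene SLCO2B1 (9.497-fold, 8.5 to 10.6), the scavenger receptor gene MSR1 (9.84-fold, 8.64 to 11.2), PDK4 (8.39-fold, 7.43 to 9.504), the nuclear receptor gene NR4A2 (7.05-fold, 6.40 to 7.79), IFIT1, TARID, PDE7B, RAB27B, IL1RAPL1 and SEMA3D. TARID is antisense to TCF21, and whether the counting used strand is not given in the sources used here. The NF-kB list had a median of 0.32 with 6 of 19 higher, and the ELR chemokines one of 0.72 with 3 of 6 higher. Although IFIT1 was lower, the interferon list had a median of 0.47, with 5 of 13 higher and only 1 lower. The summed level of 10 immune markers was 170.1 CPM against 47.0 in the control, of which CD14 made up 136, while the leukocyte gene PTPRC stood at 0.0668 CPM. In all, 157 genes were higher and 187 lower. With TMM factors the median of all measured genes moved from -0.09 to 0.03 and the counts were 189 and 130, with 59.2% higher in place of 45.6%.

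The library labelled TGFb lay close to the control. PMEPA1 was at 0.952-fold (0.915 to 0.991) of control, SMAD7, an inhibitor that TGFb signalling induces, at 0.951-fold (0.897 to 1.01) and ACTA2 at 1.197-fold (1.17 to 1.22). No member of the TGFb-SMAD, contractile, matrix or collagen processing lists was higher or lower by 1.5-fold, out of 17, 17, 26 and 15 measured, and the TGFb-SMAD median of -0.05 lay at percentile 0.860 of matched random lists. By the 2-fold rule 0 genes were higher and 1 lower, SST (ENSG00000157005), the gene of the hormone somatostatin, with 476 UMIs against 1601 (3.18-fold, 2.87 to 3.53). SST was also lower in the other stimulated libraries, and 10 control cells held 90.1% of its control UMIs. Small shifts of whole groups were present: the 6 ELR chemokines had a median of -0.38, below all matched random lists, with CXCL8 at 0.680-fold of control, and the gp130-STAT3 list one of 0.11, above all of them, with SOCS3 at 1.13-fold (1.08 to 1.19). The inflammatory fibroblast (-0.29), S phase (-0.23) and G2M (-0.20) medians also lay below all matched random lists. So did those of cytokines and growth factors (-0.11), cholesterol synthesis (-0.10) and the unfolded protein response (-0.08). The interferon median (0.15) lay above all matched random lists. Random lists do not carry the shared movement of list members, so such places can occur at small medians. The log2 folds of the library labelled TGFb had r = -0.44 with those labelled IL1b and -0.28 with those labelled TNFa. With OSM, IL36 and TL1a r was -0.07, 0.08 and 0.13. Libraries simulated as unchanged against the same control gave 0.49 to 0.51.

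A small set of genes, among them the chemokines CXCL10, CXCL8 and CXCL6, was higher in the library labelled TL1a, which is named for a ligand of the TNF family. C15orf48 was 5.05-fold (4.56 to 5.60) higher, CSF3 3.05-fold (2.81 to 3.32), CXCL10 2.42-fold (2.33 to 2.51), CXCL8 2.38-fold (2.36 to 2.40) and CXCL6 2.17-fold (2.11 to 2.24). Of the 2387 cells 10 held 27.2% of its C15orf48 and 26.5% of its CSF3 UMIs. These 5 genes were the only ones 2-fold higher, and all 5 were also 2-fold higher in the libraries labelled TNFa and IL1b, where independent lists would share 0.0619 and 0.0858. Of them 3 were also 2-fold higher in the library labelled IL36, against 0.0598. The single lower gene was SST. All 6 ELR chemokines were higher by 1.5-fold (median 0.91), against 1 of 19 NF-kB targets (median 0.22, above all matched random lists). Its log2 folds had r = 0.61 with those of the library labelled TNFa and r = 0.57 with those labelled IL1b, where unchanged libraries gave 0.53 and 0.52 and the covariances were 0.0229 and 0.0310 against 0.000574 and 0.000573. Part of that excess may also come from the shared control.

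Pro-fibrotic lists were also set directly against the library labelled TGFb, which needs no control. The library labelled OSM exceeded it, with 12 of 19 TGFb-SMAD members higher and 1 lower (median log2 1.34), 11 of 19 contractile members (1.06), 15 of 28 matrix members (0.60) and 5 of 15 collagen processing members, with 1 lower (0.40). ACTA2 was 4.67-fold (4.60 to 4.75) higher there, IL11 7.61-fold (7.53 to 7.69) and COL1A1 1.81-fold (1.80 to 1.82). The library labelled IL36 had 6 of 19 TGFb-SMAD members higher and 1 lower (0.31), 3 of 27 matrix members (0.24) and 2 of 15 collagen processing members (0.30), and its contractile median was -0.12, which turned to 0.00 with TMM factors. For the library labelled IL1b the contractile median was -0.38, and the matrix median was -0.27, which turned to 0.03 with TMM factors. Its TGFb-SMAD median was -0.19, or 0.02 with TMM factors, and its collagen processing median 0.02, or 0.24. The libraries labelled TNFa and TL1a had medians between -0.07 and 0.09 over these 4 lists, and for TNFa the matrix and TGFb-SMAD medians turned from -0.07 and -0.06 to 0.06 and 0.07 with TMM factors.

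The inflammatory and contractile differences were also seen as shares of cells, each cell thinned to 13500 UMIs. CXCL8 was detected in 67.3% (65.3 to 69.3) of control cells, 99.9% (99.67 to 99.98) of cells in the library labelled TNFa and 82.6% (81.0 to 84.2) in that labelled TL1a. BIRC3 was detected in 1.38% (0.940 to 1.95) of control cells, 25.1% (23.4 to 26.8) in the library labelled TNFa and 25.4% (23.6 to 27.4) in that labelled IL1b. ACTA2 was detected in 52.4% (50.4 to 54.5) of control cells and 82.0% (80.6 to 83.5) in the library labelled OSM, and SOCS3 in 29.1% (27.2 to 31.0) of control cells and 91.8% (90.5 to 92.9) in the library labelled IL36. Without thinning these shares were 78.9%, 99.1% and 92.1% for CXCL8, 3.62%, 41.5% and 43.1% for BIRC3, 73.4% and 91.8% for ACTA2, and 51.8% and 95.9% for SOCS3. No background share is known for any library, since the culture holds no second cell type that should lack these genes and free RNA would scale with each library's own level, so the shares are of cells with a UMI and not of cells that express the gene.

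Cell cycle genes were lower in the libraries labelled IL36 and OSM. All 20 measured G2M genes were lower by 1.5-fold in each, with medians of -1.08 and -0.95, among them the proliferation marker MKI67 at 0.350-fold and 0.364-fold and CENPF at 0.307-fold and 0.351-fold of control. S phase genes had medians of -0.57 and -0.62 there, with 8 and 11 of 19 lower. The share of thinned cells with at least 5 G2M UMIs was 17.3% (15.8 to 18.9) in the control, 9.07% (7.85 to 10.4) in the library labelled IL36 and 9.12% (8.07 to 10.3) in that labelled OSM. It was 13.3% (12.01 to 14.6) for TNFa, where 11 of 20 G2M genes were lower, and 13.0% (11.6 to 14.4) for TGFb, where 0 were lower by 1.5-fold. For TL1a at 16.8% (15.3 to 18.4) and IL1b at 18.9% (17.3 to 20.7) the intervals overlapped that of the control. For IL1b the summed G2M level was nevertheless 78.6% of control. Its G2M median was -0.32, or -0.10 with TMM factors, with 2 of 20 lower, and its S phase median was 0.19. The cycling class is a range of a score, with 261 control cells near its limit, and unthinned shares were 39.3% in the control, 30.1% for IL36 and 18.5% for OSM.

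**Figure D3:**
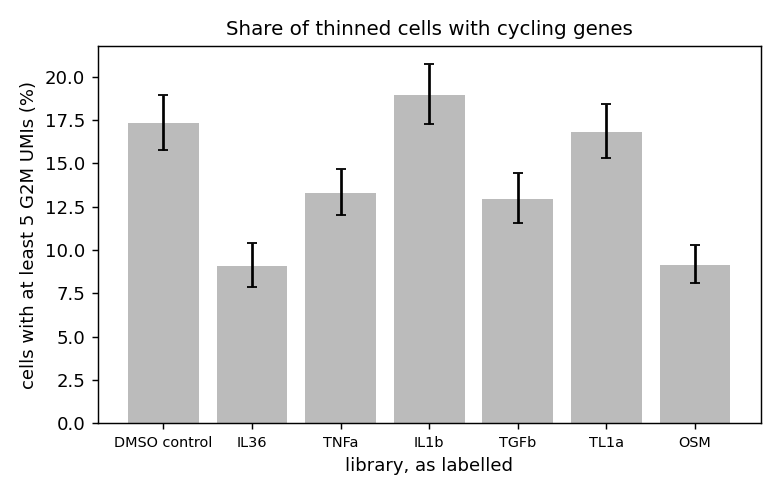
Share of cells (vertical axis, percent) with at least 5 UMIs over the G2M gene list after thinning each cell to 13500 UMIs, per library (horizontal axis, as labelled), with bars for the share and lines for its exact 95% binomial interval over cells of 1 library. The bars of the libraries labelled IL36 and OSM, 9.07% and 9.12%, lie below the control at 17.3%.

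Compared with all 6 other libraries at once, 153 genes were at least 2-fold above and 46 below in the library labelled OSM, led by KANK4, LDLRAD4, ACTA1, PLN, a regulator of the muscle calcium pump, and NOX4, and on the lower side by CCL2, CCL7, VCAM1, IL1B and CEMIP. The library labelled IL36 had 59 above and 16 below, led by SAA1, C2orf83, CXCL12, CHI3L2 and LBP and by MSR1, MARCH4, FST, an activin antagonist, LRRC17 and SLCO2B1. That labelled IL1b had 48 above, led by CSF3, CCL3, CXCL2, CSF2 and DAZL, and 6 below, led by PCDH7, NNMT, PLA2R1, SOX6 and PCDH9, and that labelled TNFa 8 above and 0 below, led by CXCL11, IL34, CXCL10, ANKRD1 and TMEM178B. The libraries labelled TGFb and TL1a had 0 genes in either direction, and the control had 1 above, SST, and 0 below. Leaving out the library labelled OSM, chosen after the data were seen, gave 38 genes below in the library labelled IL36 and 17 in that labelled IL1b, and leaving out that labelled IL36 gave 10 in that labelled IL1b.

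**Figure D4:**
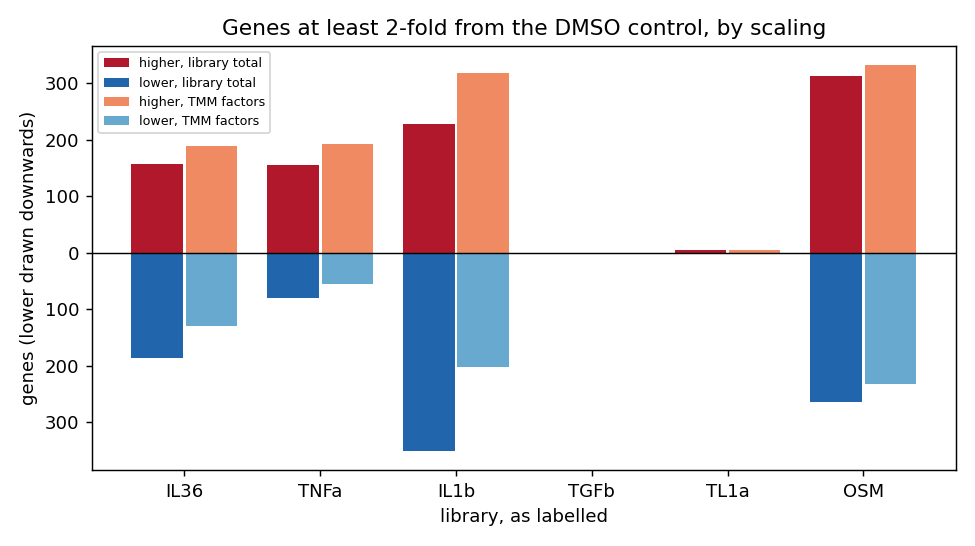
Number of genes at least 2-fold higher (drawn upwards) or lower (drawn downwards) than the DMSO control (vertical axis) in each stimulated library (horizontal axis, as labelled), scaled by library totals or by TMM factors. In the library labelled IL1b the counts are 228 higher and 351 lower with library totals, and 318 and 202 with TMM factors.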

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

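The 87 log2 folds of the highest and lowest genes of each comparison kept their direction: under the alternatives 558 values stayed within the counting interval, 312 moved beyond it and 0 reversed. These genes were chosen for folds of at least 2-fold in the same counts, so their unchanged direction is little evidence. Of the list medians against control 1252 stayed, 610 moved and 10 reversed, and of those against the library labelled TGFb 207 stayed, 31 moved and 2 reversed. Only medians outside the middle 95% of matched random lists were counted as reversed, and 23 of 156 medians against control had another sign under at least 1 scaling, the largest of them 0.26 in size. Because depth makes counting intervals narrow, a small shift counts as moved. Counts of genes stayed within 1.5 times in 66 cases (higher), 57 (lower), 98 (below all other libraries) and 95 (above), and the 115 remaining values of r stayed within the interval. Every alternative setting was run, and the removal of mitochondrial and ribosomal protein genes, the smaller addition and both cell filters gave no value listed below. No paired analysis was possible because each condition is 1 library. The cause was not tested, except that stricter limits or levels leave fewer genes and looser ones more.

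With TMM factors 202 genes were lower in the library labelled IL1b and 3 below all other libraries, the matrix list there had a median of 0.016 against control and 0.026 against the library labelled TGFb, and the niche factor list in that labelled OSM 0.11. With median-of-ratios factors the same values were 207, 3, 0.012, 0.025 and 0.11.

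From 1 CPM, higher genes were 237 (IL36) and 9 (TL1a), lower genes 128 (TNFa), 535 (IL1b) and 2 (TGFb), genes above all others 1 (TL1a) and below all others 10 (IL1b). The niche factor median was 0.057 (OSM), and r was -0.17 (TNFa and TGFb), -0.31 (IL1b and TGFb) and 0.25 (TGFb and TL1a).

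From 50 CPM, higher genes were 84 (IL36), 88 (TNFa), 124 (IL1b), 3 (TL1a) and 182 (OSM), and lower genes 61 (IL36), 32 (TNFa), 139 (IL1b), 0 (TGFb), 0 (TL1a) and 111 (OSM). Those above all others were 0 (control), 32 (IL36), 2 (TNFa), 23 (IL1b) and 85 (OSM), and below 7 (IL36), 2 (IL1b) and 19 (OSM). List medians were -0.062 (interferon, TNFa), -0.0077 (interferon, TL1a), 0.023 (receptors, OSM), 0.24 (niche factors, OSM) and -0.089 (S phase, IL1b), and r was -0.41 (TNFa and TGFb) and 0.019 (TGFb and TL1a).

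With an addition of 5 CPM, lower genes were 98 (IL36), 41 (TNFa), 215 (IL1b) and 0 (TL1a), those above all others 0 (control), 39 (IL36) and 5 (TNFa), and below 10 (IL36) and 2 (IL1b). Without the 5% of cells with the most UMIs, with every cell weighing the same, and with cells outside the cycling class only, 0 genes were above all others in the control.

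At 1.5-fold, higher genes were 366 (IL36), 367 (TNFa), 435 (IL1b), 2 (TGFb), 20 (TL1a) and 665 (OSM), and lower genes 575 (IL36), 384 (TNFa), 1051 (IL1b), 5 (TGFb), 3 (TL1a) and 709 (OSM). Those above all others were 147 (IL36), 25 (TNFa), 92 (IL1b) and 354 (OSM), and below 47 (IL36), 99 (IL1b), 2 (TGFb) and 130 (OSM).

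At 3-fold, higher genes were 53 (IL36), 56 (TNFa), 114 (IL1b), 1 (TL1a) and 119 (OSM), and lower genes 38 (IL36), 11 (TNFa), 85 (IL1b), 0 (TGFb), 0 (TL1a) and 66 (OSM). Those above all others were 0 (control), 17 (IL36), 2 (TNFa), 24 (IL1b) and 62 (OSM), and below 2 (IL36), 0 (IL1b) and 17 (OSM).

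Alternatives chosen after seeing the data left 1 library out: without that labelled IL36, 10 genes were below all others in that labelled IL1b, and without that labelled OSM, 38 (IL36) and 17 (IL1b). The share of cells with cycling genes from 10 thinned UMIs was 12.9% (control), 6.20% (IL36), 9.48% (TNFa), 13.1% (IL1b), 10.0% (TGFb), 12.1% (TL1a) and 6.68% (OSM). Unthinned, it was 39.3% (control), 30.1% (IL36), 31.4% (TNFa), 37.3% (IL1b), 36.3% (TGFb), 42.4% (TL1a) and 18.5% (OSM).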

Other observations

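Stress and metabolic gene groups also differed between libraries. In the library labelled IL1b the targets of NRF2, the regulator of the oxidative stress response, had a median log2 fold of -0.70 with 7 of 11 lower and 0 higher, among them HMOX1 (-1.50), which degrades haem, the cystine transporter SLC7A11 (-1.17) and NQO1 (-1.14). Targets of p53 had a median of -0.66 with 9 of 16 lower and 1 higher, the lower ones including BTG2 (-1.76), FDXR (-1.55) and the cell cycle inhibitor CDKN1A (-1.07). With TMM factors these medians were -0.49 and -0.46. The 3 measured metallothioneins, which bind metals, were all higher there, led by MT2A (1.17), and all 3 were higher in the library labelled IL36, led by MT1E (0.92). Of 20 genes of the unfolded protein response 4 were higher and 1 lower in the library labelled IL1b, led by DNAJB9 (1.29), and 6 in that labelled OSM, where the amino acid response gene ASNS (1.53) led.

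The niche factor list holds mostly signals from the colon stroma to the crypt epithelium, with Wnt ligands beside Wnt antagonists. Its median therefore does not measure support of that epithelium. Of 14 measured members 1 was higher and 4 lower in the library labelled IL36 (median -0.32). In that labelled IL1b 3 were higher and 6 lower (median -0.42, or -0.11 with TMM factors). The Wnt antagonist DKK1 was at -1.77 in the library labelled IL36, and in that labelled IL1b the growth factor FGF2 was at 1.89 while WNT2B stood at -1.31 and BMP4 at -1.39. Genes of the prostaglandin pathway had a median of -0.62 with 5 of 9 lower in the library labelled OSM, led by the prostaglandin E synthase PTGES (-1.87). In the complement list 4 of 11 were higher in the library labelled IL36, among them SERPING1 (1.04), the inhibitor of C1, and C1R (0.83). In the NRF2 list 4 of 11 were lower in the library labelled OSM (median -0.43).

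The first pattern weighed is that TGFb-SMAD targets were higher in the library labelled OSM and not in that labelled TGFb, and all 3 of its tests were written before the lists were computed, though after some of their members had been seen, so those members were left out. For an inactive TGFb preparation with correct labels the prediction was a gp130 response in the library labelled OSM. It was not met, since the gp130-STAT3 median there was -0.22. That prediction rests on the OSM label and on the time of sampling, which is not given. It cannot speak for or against the activity of the TGFb preparation, which stays open. Depth per cell does not enter the expected fold of summed counts, so the thinned TGFb-SMAD median of 0.98, or 0.88 in all cells, tested nothing. Mislabelled samples remain a candidate: the TGFb-SMAD median lay at percentile 6.3 of matched random lists in the library labelled TGFb and above all of them in that labelled OSM, and the gp130-STAT3 median was highest, at 0.63, in the library labelled IL36. An exchange of the labels TGFb and OSM alone would place the gp130 response in the library labelled TGFb, where SOCS3 was at 1.13-fold against 8.63-fold in that labelled IL36. Which ligand each library received was not tested and no label was altered, and a response to OSM itself, the biological explanation, needs correct labels and was not tested apart from the gp130-STAT3 median.

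The second pattern is the smaller share of cells with cycling genes in the libraries labelled IL36 and OSM, for which the depth test was written after the shares were seen and the filter test before. A difference in depth per cell was not supported, since at equal depth the higher upper bound of the 2 shares was 10.4% against a lower bound of 15.8% in the control. These are the same thinned shares as in the pattern, so the depth test restates them and is no separate evidence. The cell filter was not supported either, since it removed only 19 barcodes from the control, 9 from the library labelled IL36 and 8 from that labelled OSM. So few barcodes could hardly move a sum, and over all deposited barcodes the summed G2M level was at most 47.5% of the control. The ligands named by the labels, and differences in culture density or time, stay open as untested explanations.

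The third pattern is the presence of inflammatory transcripts in the control library, for which the test of free RNA was written after the values were seen and the test of IL1B before. Free RNA spread evenly over cells was not supported as the only source. CXCL8 was held by 67.3% of thinned control cells, where an even spread would give 99.99%. Of its UMIs 64.3% lay in 10% of cells. Since these values were already known, the test restates them and is no separate evidence. A smaller part of evenly spread free RNA, besides cells that hold more CXCL8, is not excluded. Cells holding IL1B and chemokine transcripts together cannot be told from cells that do not: those with an IL1B UMI, 783 of 2246, held 1.70 times the CXCL8 UMIs of the others, between the limits of 1.2 and 2 set beforehand, and 0.932 times the COL1A1 UMIs. No other biological explanation was tested, since the design names no group within the control.

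A few cells made up some of the largest differences: 43 control cells held all SST UMIs of that library, and 60 cells all ACTA1 UMIs of the library labelled OSM.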
